A study of Mus musculus with 10 samples.

How the data were processed

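Small RNA was profiled in mouse E14 embryonic stem cells (129/Ola) of 5 groups with 2 libraries each: WT, Dgcr8_KO, Drosha_KO, Dicer_KO and Ago12_KO, the double knockout of Ago1 and Ago2. Per the labels, cells grew on gelatine in DMEM with 15% serum and 100 U/mL LIF, RNA was extracted with Trizol, and libraries were made from 1 ug of total RNA with the TruSeq small RNA kit and sequenced on a HiSeq2000. The authors deposited 1 table of raw read counts per mature miRNA, which per the labels came from Bowtie alignments to mm10. Versions, the counting tool, the miRBase release and the treatment of reads that map to several places are not given in the sources used here. The values were whole numbers without normalization. Of 865 entries with counts in at least 3 libraries, 42 held only multiples of a number above 1 (12 for miR-669a-5p and 10 for miR-467a-5p), and 5 pairs of entries had identical counts in all libraries.

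Library totals ran from 37476 to 2357868 counts, and the floor of 3 counts from 1.27 to 80.1 CPM. Replicates differed by more than counting error, with a chi-square per degree of freedom of 24.0 in WT, 3.88 in Dgcr8_KO, 31.8 in Drosha_KO, 17.2 in Dicer_KO and 63.9 in Ago12_KO. The labels give WT passages and Dicer_KO clones, and date-like codes for Dgcr8_KO and Ago12_KO alone, so batch and group cannot be told apart. Replicate numbers do not pair the groups by anything the labels state.

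The deposited counts were tested with edgeR 4.0.16 (quasi-likelihood, R 4.3.3), with all 5 groups in 1 fit with 5 residual degrees of freedom, column totals as library sizes without TMM factors, and Benjamini-Hochberg adjustment over the entries tested in each comparison. filterByExpr by group (a CPM minimum of 38.54 from a minimum count of 10, and a minimum total of 15) kept 481 of 1907 entries. An adjusted p under 0.05 made a call. Column totals were chosen before the data were examined, because TMM and size factors assume that most entries do not change. Each mutant was compared with WT, and Dgcr8_KO with Drosha_KO, Dicer_KO with Drosha_KO and Ago12_KO with Dicer_KO directly. Standard errors were taken from the fold change and its F value. Where all libraries of a group had no count, the fold is a bound from 3 counts over the group.

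A set of 18 lists was fixed before the data were examined: the miR-290 to miR-295 and the miR-302 and miR-367 clusters, the miR-17-92, miR-106a-363 and miR-106b-25 clusters, the miR-15/16 and let-7/miR-98 families, the Dlk1-Dio3 and Sfmbt2 clusters, mirtrons, hairpins reported to bypass Drosha, snoRNA-derived entries, miR-451, entries reported to overlap tRNA or rRNA, miR-1306, and markers of fibroblasts or feeders, blood, neural, muscle, and liver, gut and endoderm cells. The 14 lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over lists and the 4 comparisons with WT, and again with an estimated correlation. Shares of counts were compared by an exact two-sided permutation test, whose smallest p for 2 against 2 libraries is 0.333, so no share can pass 0.05. Arm balance was tested with limma on log2((5p + 0.5)/(3p + 0.5)) for hairpins with a mean of at least 20 counts per arm. Single shares have 95% Clopper-Pearson intervals (scipy 1.17.1). Positions came from GENCODE M21 and RefSeq hairpins on GRCm38 patch 6, and 496 of 498 entries looked up had a hairpin.

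In each comparison with WT, the miRNAs to name were set by a rule made before the data were examined: up to 10 with the highest and 10 with the lowest fold change among calls with separated replicates and a mean of at least 50 CPM, up to 4 members of each list, and the 5 most abundant entries of each group. The rule named 90 miRNAs in Dgcr8_KO, 92 in Drosha_KO, 88 in Dicer_KO and 92 in Ago12_KO, of which 27, 28, 26 and 29 are printed, a subset chosen after their values were seen. miR-295-5p in Dicer_KO and the miRNAs named in the direct comparisons of mutants were also chosen after their values were seen.

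Alternatives were TMM factors, DESeq2 size factors in edgeR, no scaling (which keeps differences in total count in the fold changes), no filter, a minimum mean of 10 CPM, only the groups compared, the replicate number as a block, DESeq2 1.42.0 with its own size factors or with column totals, a 2-fold minimum, other denominators for shares, another pseudocount and minimum for arms, and leaving out each library in turn, where a lone sample is assumed to vary like the other groups. Corrected repeat counts, fragment-like entries out of the totals, at least 100 counts per mutant library for arms and the count of Dlk1-Dio3 members were added after the data were seen.

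The tests were run on simulated data with known changes. edgeR recovered 47.8%, 26.9%, 19.4% and 34.3% of 2-fold changes for Dgcr8_KO, Drosha_KO, Dicer_KO and Ago12_KO against WT, 85.1%, 65.7%, 59.7% and 89.6% of 4-fold changes and 89.4%, 74.2%, 78.8% and 90.9% of 8-fold changes. With the true library sizes it called 2.05%, 0.81%, 0.439% and 1.6% of unchanged entries, but with column totals, which move when abundant entries change, 37.7%, 32.8%, 0.439% and 24.4%. Each comparison had a single random draw of changed entries, so the 0.439% does not show that column totals are safe for Dicer_KO. In the real data its entries called lower went from 205 to 106 with DESeq2 size factors. For Dgcr8_KO against Drosha_KO, Dicer_KO against Drosha_KO and Ago12_KO against Dicer_KO, 68.7%, 47.8% and 62.7% of 4-fold changes were recovered, and 2.31%, 1.25% and 0.719% of unchanged entries were called, or 20.8%, 4.17% and 18% with column totals. The calls are therefore of changed shares, not of changed amounts. Camera called 0 of 15 unchanged lists. These were random lists of entries drawn independently and tested with the true library sizes. That simulation could not show false calls from correlated members or from column totals. The arm test (limma) recovered 13.3%, 26.7%, 16.7% and 13.3% of 4-fold changes and 70%, 46.7%, 60% and 46.7% of 8-fold changes in Dgcr8_KO, Drosha_KO, Dicer_KO and Ago12_KO, and called no unchanged hairpin. Each simulated hairpin had the same mean share of the counts in all groups, so none was depleted in a mutant. The simulation thus does not cover false calls of hairpins left with few or no mutant counts. Tables were handled in Python 3.11.15 with pandas 2.3.3 and drawn with matplotlib 3.10.9.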

Results

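Small RNA was sequenced from mouse E14 embryonic stem cells, a 129/Ola line kept in serum and LIF, to profile miRNAs in cells that lack parts of the RNAi pathway. The 5 groups of 2 libraries were wild type (WT), Dgcr8_KO and Drosha_KO, which lack a subunit of the Microprocessor that cuts primary transcripts into hairpins, Dicer_KO, which lacks the enzyme that cuts hairpins into mature duplexes, and Ago12_KO, which lacks the Argonaute proteins Ago1 and Ago2 that hold mature strands. Of 1907 mature miRNA entries, 1262 had at least 1 count. The total count was 2357868 and 1943868 in the WT replicates, 289539 and 408654 in Dgcr8_KO, 39511 and 40306 in Drosha_KO, 45222 and 37476 in Dicer_KO, and 349312 and 229407 in Ago12_KO. Mean totals were thus 6.16 times below WT in Dgcr8_KO, 53.9 times in Drosha_KO, 52.0 times in Dicer_KO and 7.43 times in Ago12_KO. These totals cover miRNA entries only. The number of all sequenced reads was not used here, so fewer reads sequenced and fewer miRNAs cannot be told apart. A single count was worth 0.424 CPM (counts scaled to a library total of 1000000) in WT replicate 1 and 26.7 CPM in Dicer_KO replicate 2. The labels name 2 passages for WT and 2 clones for Dicer_KO, and nothing says that the other replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Intervals and floors cover counting error only. The mRNAs of the knocked-out genes were not measured, so the labels could not be checked on them.

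**Figure D1:**
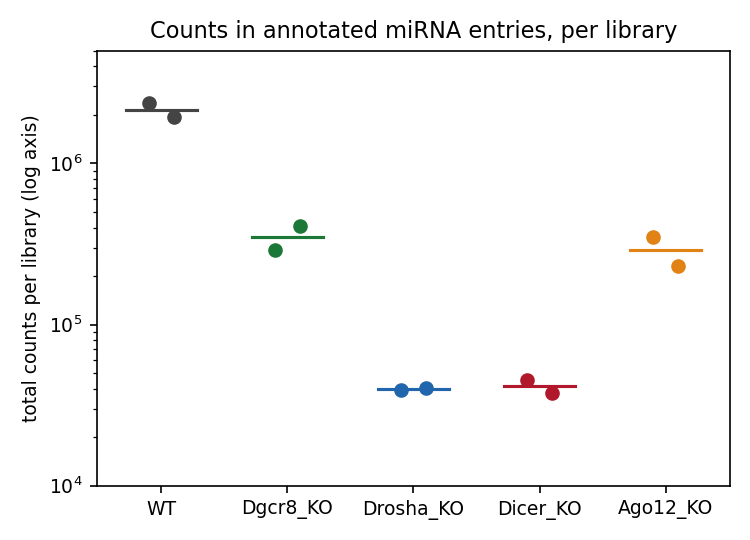
Total counts in annotated miRNA entries (vertical, log axis) for each of the 10 libraries (points) with the group mean (line). WT replicates hold 2357868 and 1943868 counts and the Drosha_KO replicates 39511 and 40306.

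miR-92a-3p, miR-182-5p, miR-295-3p and miR-127-3p were the most abundant entries of WT cells, with 15.6% ± 0.718, 12.3% ± 0.377, 10.2% ± 0.456 and 8.06% ± 0.142 of the counts (SD, n = 2). miR-182-5p led in Dgcr8_KO (19.7% ± 0.583) and Drosha_KO (27.1% ± 4.05). In Dicer_KO the leading entries were miR-3963 (28.8% ± 4.90) and miR-6240 (16.7% ± 2.88), the latter on the list of entries that overlap tRNA or rRNA, and in Ago12_KO they were miR-92a-3p (15.4% ± 2.68) and miR-182-5p (14.2% ± 3.80). A set of 8 miRNAs has these places in GRCm38 (GENCODE M21). The hairpin of miR-295 lies on chromosome 7 at 3220773 to 3220841, opposite an exon of Nlrp12. That of miR-182 lies on chromosome 6 at 30165918 to 30165992 in no other annotated gene. The hairpins of miR-92a-3p lie on chromosome 14 at 115044427 to 115044506 in the Mir17hg transcript and on chromosome X at 52741838 to 52741928. miR-127 lies on chromosome 12 at 109592846 to 109592915, antisense to an exon of Rtl1. miR-877 lies on chromosome 17 at 35960730 to 35960814 in an intron of Abcf1, and miR-484 on chromosome 16 at 14159626 to 14159692 at an exon of Marf1. miR-3068 lies on chromosome 12 at 87437679 to 87437757 in an intron of Alkbh1, and miR-3963 on chromosome 3 at 151023792 to 151023862 in no other annotated gene.

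The fold changes below compare shares of the counted reads, so they say nothing of miRNA amounts per cell. Among the 481 entries tested, the median log2 fold change against WT was -0.41 in Dgcr8_KO, -0.87 in Drosha_KO, -2.78 in Dicer_KO and -0.02 in Ago12_KO. Entries with no count in 1 group have no measured fold change, and with each at its bound these medians were -0.34, -0.017, -0.90 and 0. TMM factors placed these medians at -0.71, -1.47, -3.06 and -0.66, DESeq2 size factors at -0.44, -0.75, -1.67 and -0.24, and counts left unscaled at -3.02, -6.40, -7.52 and -2.88. List medians are therefore also given relative to the median of all entries.

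The comparison of Dgcr8_KO with WT asks which miRNAs depend on Dgcr8. Mirtrons, spliced introns that need no Microprocessor, took 0.774% ± 0.000601 of the counts in Dgcr8_KO and 0.0464% ± 0.00684 in WT (SD, n = 2), and all 7 tested members rose. miR-877-5p went from 243 ± 39.3 to 4706 ± 90.1 CPM (log2 fold change 4.28, SE 0.38, edgeR adjusted p = 4.35e-06), and miR-702-3p rose by 4.10 (edgeR adjusted p = 7.98e-06). Of 5 tested hairpins reported to bypass the Microprocessor, 4 rose, among them miR-484 (1114 ± 116 to 15598 ± 966 CPM, log2 fold change 3.81, edgeR adjusted p = 4.86e-06), miR-320-3p (4.64, edgeR adjusted p = 8.38e-06) and miR-344-3p (5.33, edgeR adjusted p = 1.03e-05). All 5 snoRNA-derived entries rose, with miR-1839-5p at 4.80 (edgeR adjusted p = 1.77e-06) and miR-664-5p at 3.94 (edgeR adjusted p = 1.13e-05). The 4 entries that overlap tRNA or rRNA rose too, from 0.152% ± 0.0135 to 2.43% ± 0.0257 of the counts, including miR-1983 (4.38, edgeR adjusted p = 1.55e-06) and miR-6236 (5.76, edgeR adjusted p = 2.62e-06). The median log2 fold change was 3.70 for mirtrons, 4.64 for the bypassing hairpins, 4.70 for snoRNA-derived entries and 4.01 for the tRNA or rRNA entries, or 4.11, 5.04, 5.11 and 4.42 above the median of all. limma's camera test called these lists higher with adjusted p = 0.000947, 0.0153, 0.0135 and 0.0135 in that order. None of the 4 calls held with estimated correlations, where the adjusted p = 0.268, 0.268, 0.491 and 0.268 with an estimated correlation.

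Canonical clusters went different ways in the same cells. The miR-17-92, miR-106a-363 and miR-106b-25 clusters, which carry proliferation-linked miRNAs, dropped from 18.9% ± 0.914 to 2.10% ± 0.0487 of the counts, with 22 of 26 tested members lower and 2 higher (23 and 2 adjusted over the list alone). miR-92a-3p went from 156020 ± 7179 to 13265 ± 140 CPM (log2 fold change -3.56, SE 0.23, edgeR adjusted p = 7.17e-07), miR-25-3p changed by -4.69 (edgeR adjusted p = 2.30e-06), and miR-18b-5p, with no count in Dgcr8_KO, was at least 157-fold lower. The list median was -3.62, or -2.89 with undetected members at their bound and -3.22 relative to all (-2.54 with bounds), and camera gave adjusted p = 0.000187, against adjusted p = 0.268 with an estimated correlation. Members of the miR-290 to miR-295 cluster, abundant in mouse embryonic stem cells, went both ways: 6 of 14 rose and 4 fell (7 and 4 adjusted over the list alone), with a median of 0.24 that turned to -0.07 under TMM and -2.38 without scaling. miR-291a-5p rose by 1.47 (edgeR adjusted p = 0.000209), while miR-295-3p went from 101530 ± 4564 to 60132 ± 2053 CPM (-0.76, SE 0.24, edgeR adjusted p = 0.0140). The miR-295-3p call was lost without Dgcr8_KO replicate 1 (edgeR adjusted p = 0.0729), Dgcr8_KO replicate 2 (0.0979) or WT replicate 2 (0.0644), or with fragment-like entries out of the totals (0.0952), with a range of 6.60e-07 to 0.0979 over the alternatives. miR-182-5p rose by 0.68 (SE 0.23, edgeR adjusted p = 0.0210), a call lost under TMM (0.142) and without Dgcr8_KO replicate 1 (0.0665), Dgcr8_KO replicate 2 (0.0908), WT replicate 1 (0.0551) or WT replicate 2 (0.0751), over a range of 3.36e-07 to 0.142. Of the miR-15/16 family 6 of 12 fell, with miR-15b-5p, at 0 counts, at least 121-fold lower and miR-16-5p at -0.24 (edgeR adjusted p = 0.406), called when only these groups were fitted (0.0249, range 1.48e-04 to 0.875).

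The Dlk1-Dio3 cluster, an imprinted miRNA cluster on chromosome 12, held 22.4% ± 0.318 of the Dgcr8_KO counts and 19.1% ± 0.0313 of the WT counts, although 47 of 63 tested members fell and 4 rose. miR-134-5p, with no count in Dgcr8_KO, was at least 196-fold lower, and miR-411-5p changed by -4.29 (SE 1.17, edgeR adjusted p = 0.00669), a call lost without Dgcr8_KO replicate 2 (edgeR adjusted p = 0.0581, range 3.03e-24 to 0.0581). miR-127-3p, at 178990 ± 3677 CPM in Dgcr8_KO and 80581 ± 1419 CPM in WT, was not called (1.15, SE 1.37, edgeR adjusted p = 0.464). The fit pooled its spread over all 5 groups, and without Drosha_KO replicate 1 or Drosha_KO replicate 2 its edgeR adjusted p = 3.35e-04 or 1.65e-04, within a range of 3.77e-09 to 0.605. The list median was -3.15, or -2.75 relative to all, and camera gave adjusted p = 0.000116, against adjusted p = 0.668 with an estimated correlation.

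Over all 481 entries, 156 were higher and 197 lower in Dgcr8_KO by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Counts left unscaled gave 51 and 329. Other entries with large changes were miR-5126 (6.15, SE 1.10, edgeR adjusted p = 0.000476, and 9.27 without WT replicate 1) and miR-3068-5p (5.08, edgeR adjusted p = 1.67e-05). Among lists of other cell types, fibroblast or feeder markers had 1 of 11 higher and 4 lower, with miR-27b-3p at -5.80 (edgeR adjusted p = 4.04e-07) and miR-22-3p at -1.37 (edgeR adjusted p = 0.000534). Blood markers had 2 of 6 higher and 1 lower (2 and 0 adjusted over the list alone), with miR-142a-5p at 3.22 (edgeR adjusted p = 0.000152), a call lost without scaling (0.381, range 2.37e-14 to 0.381). Neural markers had 3 of 7 lower (2 adjusted over the list alone), with miR-128-3p at -4.20 (edgeR adjusted p = 9.76e-06), and of 3 liver, gut and endoderm markers 1 was higher and 1 lower (1 and 2 under TMM, 0 and 2 without scaling), with miR-192-5p at -5.83 (edgeR adjusted p = 4.35e-06).

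**Figure D2:**
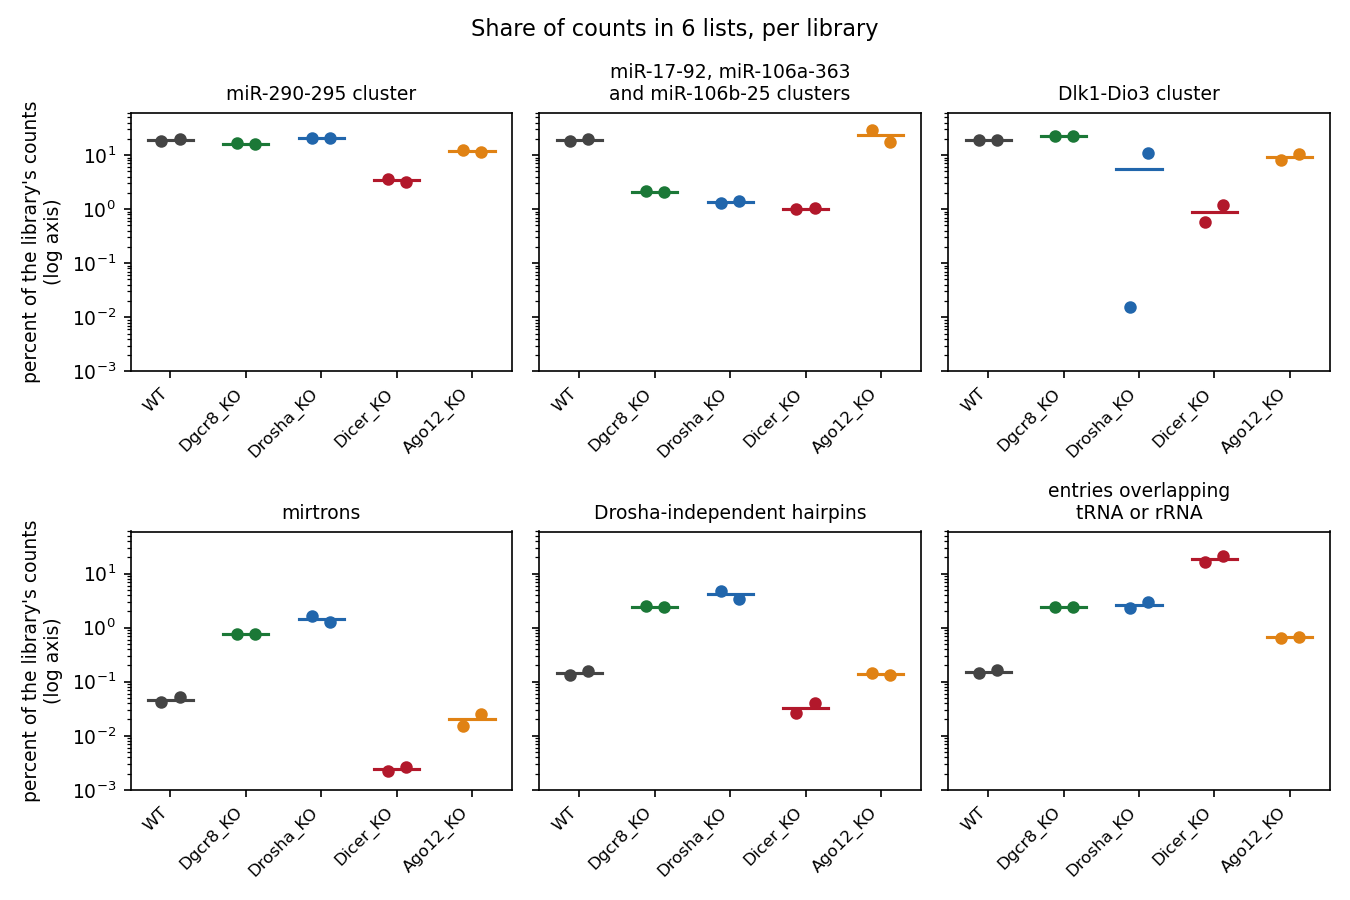
Share of each library's counts (percent, log axis) in 6 lists, with 1 point per library and the group mean as a line. Mirtrons take 0.774% in Dgcr8_KO and 1.44% in Drosha_KO against 0.0464% in WT, and entries overlapping tRNA or rRNA 18.8% in Dicer_KO, while without scaling to library totals the counts of both lists are lower in Drosha_KO than in WT.

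In Drosha_KO, miRNAs that bypass the Microprocessor also took larger shares. All 7 tested mirtrons and 4 of 5 bypassing hairpins were higher. With counts left unscaled the direction flips for mirtrons (0 higher and 4 lower) and is lost for bypassing hairpins (1 higher and 1 lower). miR-877-5p reached 9399 ± 2170 CPM (log2 fold change 5.27, SE 0.40, edgeR adjusted p = 1.35e-06), miR-702-3p changed by 4.59 (edgeR adjusted p = 4.53e-06), miR-484 reached 29756 ± 5416 CPM (4.74, SE 0.36, edgeR adjusted p = 1.35e-06), and miR-320-3p changed by 4.93 (edgeR adjusted p = 5.71e-06). Of snoRNA-derived entries 4 of 5 were higher, with miR-1839-5p at 5.64 (edgeR adjusted p = 8.87e-07) and miR-664-5p at 5.65 (edgeR adjusted p = 2.73e-06), and all 4 tRNA or rRNA entries were higher, with miR-1983 at 5.25 (edgeR adjusted p = 5.98e-07) and miR-6239 at 7.46 (edgeR adjusted p = 9.63e-07), but unscaled counts turned the medians of both lists from 5.65 and 4.42 to -0.08 and -1.34. miR-3068-5p went from 2.73 ± 0.944 to 8916 ± 2960 CPM (11.54, SE 0.55, edgeR adjusted p = 5.98e-07), and miR-3535, which lies in a snoRNA gene in Ncl on chromosome 1 at 86351981 to 86352127, reached 13186 ± 6157 CPM from 87.6 ± 8.14 (7.23, edgeR adjusted p = 5.98e-07). limma's camera test called mirtrons, bypassing hairpins, snoRNA-derived and tRNA or rRNA entries higher, with adjusted p = 0.000693, 0.0117, 0.0135 and 0.0142. All 4 calls were lost, at adjusted p = 0.268, 0.268, 0.491 and 0.268 with an estimated correlation.

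Of the miR-17-92, miR-106a-363 and miR-106b-25 clusters, 17 of 26 members fell in Drosha_KO and none rose. miR-92a-3p went to 6674 ± 597 CPM (log2 fold change -4.55, SE 0.24, edgeR adjusted p = 2.41e-07), miR-25-3p changed by -4.49 (edgeR adjusted p = 3.63e-06), and miR-363-3p, with no count, was at least 148-fold lower. Their median was -3.87, or -2.77 with undetected members at their bound and -3.005 relative to all (-2.75 with bounds), and camera gave adjusted p = 0.00202, against adjusted p = 0.308 with an estimated correlation. The miR-290 to miR-295 cluster held 20.8% ± 0.408 of the counts, close to 19.1% ± 0.960 in WT, with 7 of 14 members higher and 4 lower, a majority that flips to 0 higher and 14 lower without scaling. miR-291a-5p rose by 1.70 (edgeR adjusted p = 8.93e-05) and miR-294-3p by 1.58 (edgeR adjusted p = 0.00156), while miR-295-3p changed by -1.93 (edgeR adjusted p = 4.85e-05). miR-182-5p rose by 1.14 (edgeR adjusted p = 0.00156), a call lost under TMM (0.0616, range 6.84e-07 to 0.0616). miR-16-5p changed by -1.85 (edgeR adjusted p = 1.19e-04), 1 of 5 members of the miR-15/16 family of 12 that fell (4 adjusted over the list alone). let-7g-5p rose by 3.55 (edgeR adjusted p = 1.74e-05), the only member of the let-7/miR-98 family of 10 called higher, while 1 was called lower.

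The Dlk1-Dio3 cluster split the Drosha_KO replicates. Replicate 1 held 6 cluster counts of 39511, a share of 0.0152% (95% Clopper-Pearson interval 0.00557 to 0.0331%), and replicate 2 held 4392 of 40306, a share of 10.9% (10.6 to 11.2%). Of 63 tested members 45 were lower and none was higher, with 32 lower without Drosha_KO replicate 1 and 52 lower without Drosha_KO replicate 2. miR-758-3p and miR-134-5p had no count in either library and were at least 83.8-fold and 22.4-fold lower. miR-541-5p changed by -3.80 (SE 1.15, edgeR adjusted p = 0.0150), which was lost when only Drosha_KO and WT were fitted (0.113, range 9.62e-22 to 0.113), and without Drosha_KO replicate 2 it was at -9.83. miR-127-3p was not called (-1.01, SE 1.37, edgeR adjusted p = 0.539), but without Drosha_KO replicate 2 it was at -9.63 (edgeR adjusted p = 3.11e-13) and without Drosha_KO replicate 1 at -0.012 (edgeR adjusted p = 0.974), the ends of the range over the alternatives. The list median was -5.18, or -2.26 with the 28 undetected members at their bound and -4.31 relative to all (-2.24 with bounds), and camera gave adjusted p = 1.36e-06, against adjusted p = 0.570 with an estimated correlation.

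**Figure D3:**
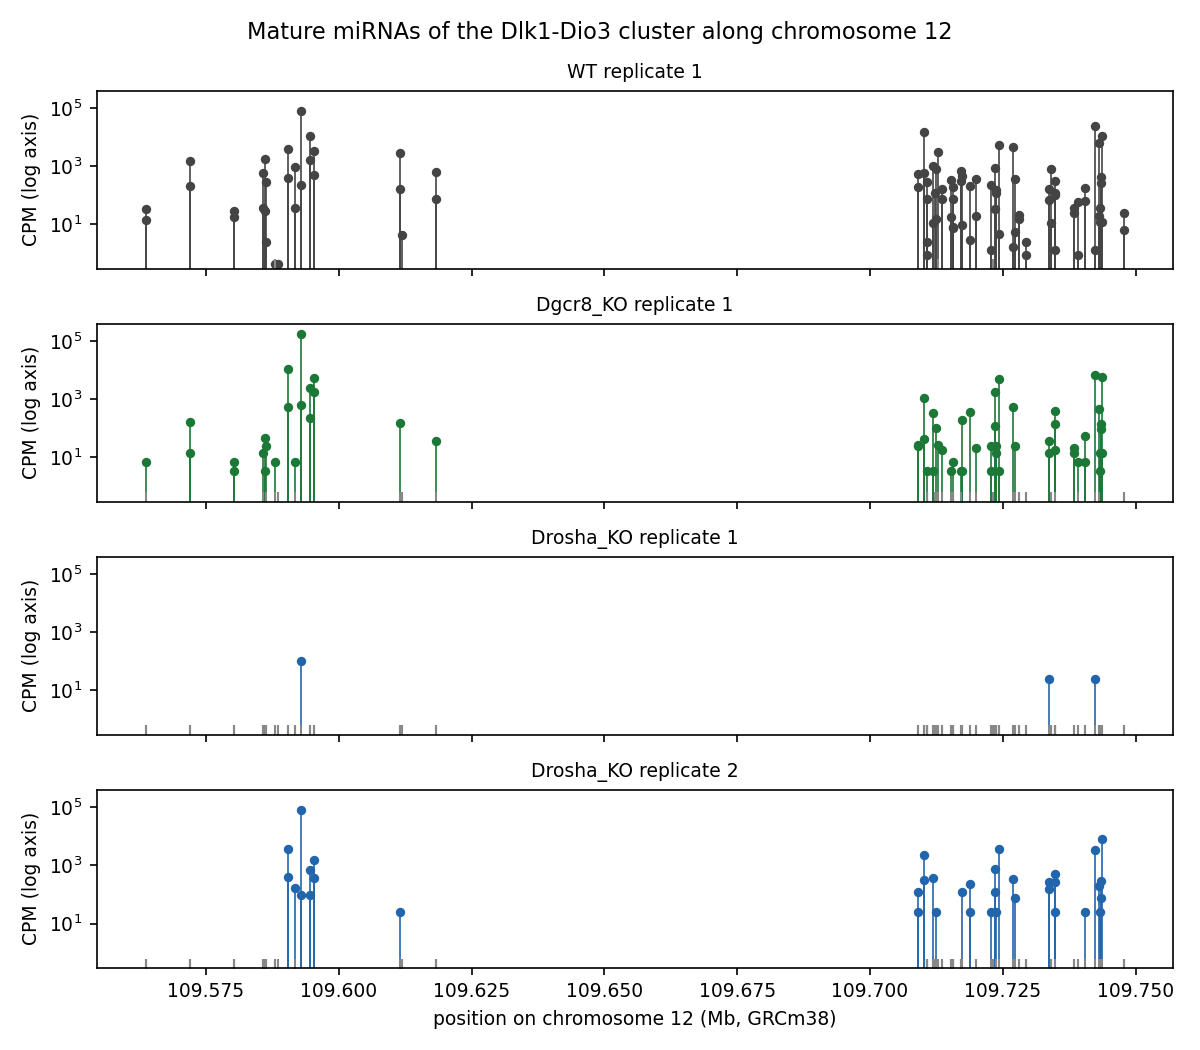
CPM (log axis) of 105 mature miRNAs of the Dlk1-Dio3 cluster by position on chromosome 12 (Mb, GRCm38, 109563692 to 109747960) in 4 libraries, with grey ticks at entries without a count. Drosha_KO replicate 1 has counts for 3 of 111 cluster entries and Drosha_KO replicate 2 for 38.

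Over all entries, 126 were higher and 31.6% of the 481 lower in Drosha_KO by edgeR's quasi-likelihood test, and unscaled counts gave 5 and 399. Of fibroblast or feeder markers 1 of 11 was higher and 4 were lower, including miR-27b-3p (-4.58, edgeR adjusted p = 9.63e-07) and miR-22-3p (-1.61, edgeR adjusted p = 2.25e-04). Of neural markers 1 of 7 was higher and 3 were lower: miR-138-5p rose by 3.11 (edgeR adjusted p = 1.07e-04) and miR-128-3p changed by -7.01 (edgeR adjusted p = 1.74e-05). The latter had 1 count in Drosha_KO, and without Drosha_KO replicate 1 the fit gave -13.02, which no count supports. Blood markers had 2 of 6 higher and 1 lower (3 and 2 adjusted over the list alone). Of 3 liver, gut and endoderm markers 1 was higher and 1 lower (0 and 1 under TMM, 0 and 3 without scaling), with miR-192-5p at -4.77 (edgeR adjusted p = 5.10e-05).

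**Figure D4:**
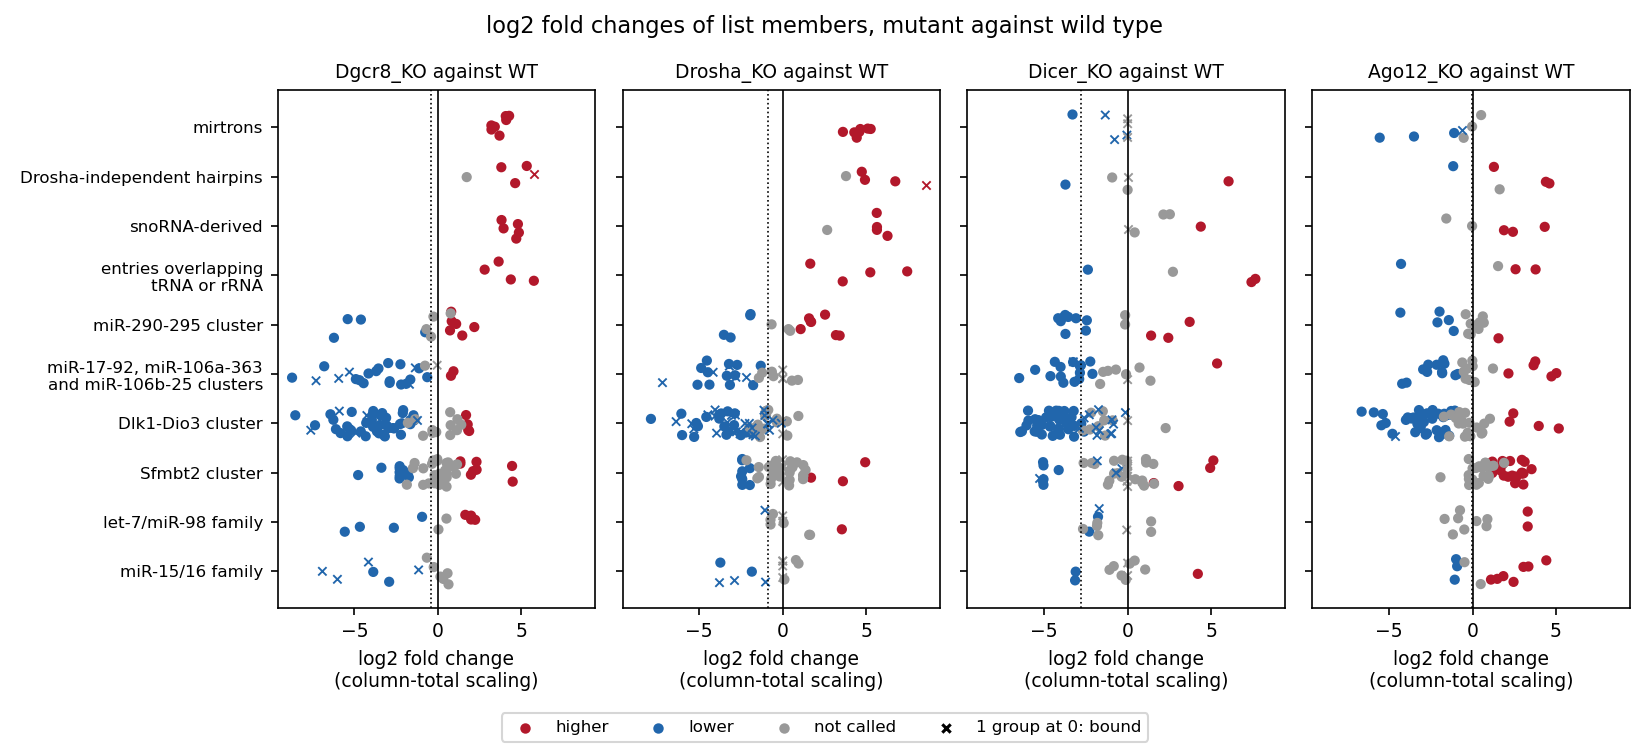
log2 fold change (horizontal, column-total scaling) of each tested member of 10 lists in each mutant against WT, colored by the edgeR call, with crosses for members at 0 in 1 group (drawn at their bound) and a dotted line at the median of all 481 entries. The 7 mirtrons lie between 3.21 and 4.28 in Dgcr8_KO. When counts are left unscaled, the higher direction flips for the Sfmbt2 cluster in Ago12_KO. In Drosha_KO it then flips for mirtrons, snoRNA-derived and tRNA or rRNA entries, while the calls of Drosha-independent hairpins split evenly.

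Dgcr8_KO and Drosha_KO were compared directly, since both lack a Microprocessor subunit. miR-3068-5p (log2 fold change -6.47, SE 0.44, edgeR adjusted p = 3.39e-05), miR-24-3p (-4.77, edgeR adjusted p = 2.39e-05) and miR-3535 (-4.12, edgeR adjusted p = 4.77e-05) were lower in Dgcr8_KO. miR-16-5p (1.61, edgeR adjusted p = 0.00218), miR-295-3p (1.17, edgeR adjusted p = 0.00686) and miR-92a-3p (0.99, edgeR adjusted p = 0.00781) were higher. Without Dgcr8_KO replicate 1 or Dgcr8_KO replicate 2 the call was lost for miR-295-3p (edgeR adjusted p = 0.0664 and 0.0562, range 4.09e-06 to 0.0664) and miR-92a-3p (0.0664 and 0.0679, range 3.03e-06 to 0.0679), the latter also with DESeq2 size factors (0.0513). miR-877-5p (-0.998, edgeR adjusted p = 0.0733) and miR-484 (-0.93, edgeR adjusted p = 0.0710) were not called, but were without Drosha_KO replicate 2 (edgeR adjusted p = 0.0121 and 0.0136), and miR-877-5p also without Ago12_KO replicate 1 (0.0410) or Ago12_KO replicate 2 (0.0425). Their ranges over the alternatives were 5.63e-04 to 0.308 and 7.46e-04 to 0.344. miR-127-3p was not called (2.16, edgeR adjusted p = 0.360), but was at 1.16 without Drosha_KO replicate 1 (0.0181) and at 10.79 without Drosha_KO replicate 2 (1.96e-13), over a range of 1.96e-13 to 0.507. In all, 27 entries were higher and 40 lower, against 38 and 35 under TMM and 348 and 5 unscaled. These counts became 12 and 23 without Dgcr8_KO replicate 1 and 11 and 18 without Dgcr8_KO replicate 2, and 50 were higher without Drosha_KO replicate 2.

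The comparison of Dicer_KO with WT asks which entries depend on Dicer. miR-6240 went from 828 ± 112 to 167330 ± 28835 CPM (log2 fold change 7.66, SE 0.33, edgeR adjusted p = 3.70e-08), miR-3963 from 2566 ± 913 to 288470 ± 49003 CPM (6.81, SE 0.41, edgeR adjusted p = 3.32e-07) and miR-6539 to 83223 ± 2486 CPM (7.19, edgeR adjusted p = 3.70e-08). miR-5126 (7.56, edgeR adjusted p = 2.27e-04, and 10.67 without WT replicate 1), miR-6236 (7.42, edgeR adjusted p = 7.21e-07) and miR-5099 (5.05, edgeR adjusted p = 3.32e-07) rose as well. The tRNA or rRNA entries with these 4 others (miR-3963, miR-5126, miR-6539 and miR-5099, grouped after their values were seen and called fragment-like here) held 72.3% and 77.3% of the Dicer_KO counts and 0.800% and 0.671% of the WT counts. They also exceeded WT elsewhere, with 13.3% and 13.0% in Dgcr8_KO, 11.7% and 12.4% in Drosha_KO, and 8.09% and 9.60% in Ago12_KO. Whether they are fragments was not tested. Taking them out of the totals raises all Dicer_KO fold changes against WT alike. Of the 4 tested tRNA or rRNA entries 2 rose and 1 fell, a direction whose median of 5.07 turned to -0.56 without scaling, and camera gave adjusted p = 0.0271, against adjusted p = 0.268 with an estimated correlation. miR-181a-2-3p rose by 9.15 (edgeR adjusted p = 4.66e-06), from 1 count in WT replicate 1 and none in WT replicate 2.

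In Dicer_KO, miR-92a-3p went to 6320 ± 69.2 CPM (log2 fold change -4.63, SE 0.24, edgeR adjusted p = 1.19e-07), miR-295-3p to 5671 ± 1452 CPM (-4.16, SE 0.27, edgeR adjusted p = 5.00e-07), and miR-25-3p (-4.01, edgeR adjusted p = 5.03e-06), miR-26a-5p (-4.21, edgeR adjusted p = 4.00e-07) and miR-16-5p (-3.15, edgeR adjusted p = 3.62e-06) fell too. miR-101b-3p and miR-669a-3p, with no count, were at least 40.1-fold and 38.8-fold lower. The counts of miR-669a-3p were all multiples of 11, as if reads were counted at several hairpins, so its bound may be too high. miR-182-5p fell by 0.86 (edgeR adjusted p = 0.00881), lost without Dicer_KO replicate 2 (0.0619), while it was at 0.52 with DESeq2 size factors (0.121) and higher by 1.11 with fragment-like entries out of the totals (0.00352), over a range of 2.26e-07 to 0.121. miR-15b-5p was not called (0.13, edgeR adjusted p = 0.755), but was at 1.51 with DESeq2 size factors (0.00495, range 2.66e-06 to 1). In the miR-17-92, miR-106a-363 and miR-106b-25 clusters 17 of 26 members fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -2.88 that was -0.11 relative to all, or -1.96 relative to all with undetected entries at their bound. In the miR-290 to miR-295 cluster 9 of 14 fell and 3 rose, with a median of -2.80 that was -0.02 relative to all (-1.90 with bounds), and miR-291a-5p changed by -2.50 (edgeR adjusted p = 6.77e-06), lost with fragment-like entries out of the totals (0.116, range 2.21e-55 to 0.116). In the Dlk1-Dio3 cluster 53 of 63 fell and none rose, with a median of -4.60 that was -1.82 relative to all (-2.80 with bounds), and camera gave adjusted p = 0.0120, against adjusted p = 0.685 with an estimated correlation. miR-127-3p fell by 4.34 (SE 1.56, edgeR adjusted p = 0.0333), a call lost without Dicer_KO replicate 1 (0.209) or Dicer_KO replicate 2 (0.136), over a range of 3.13e-43 to 0.246.

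Lists that bypass the Microprocessor went both ways in Dicer_KO. Of 5 bypassing hairpins 1 was higher and 1 lower, and of 5 snoRNA-derived entries 1 was higher and none lower, which without scaling becomes 0 higher and 3 lower, and 0 higher and 4 lower. miR-484 went to 82.0 ± 40.4 CPM (log2 fold change -3.73, SE 0.42, edgeR adjusted p = 2.06e-05), and miR-877-5p, with 1 count in each library, to 24.4 ± 3.23 CPM (-3.31, edgeR adjusted p = 0.00119), a call lost with DESeq2 size factors (0.0526, range 1.33e-07 to 0.215). miR-702-3p had no count and was at least 2.53-fold lower (edgeR adjusted p = 0.00454), a call lost with fragment-like entries out of the totals (0.109, range 7.99e-07 to 0.109). Of 7 mirtrons 4 were called lower, with a median of -5.61, or -0.05 with the 6 undetected members at their bound. miR-320-3p was not called (-0.93, edgeR adjusted p = 0.134), and had the opposite sign with DESeq2 size factors (0.48). miR-451, made by Ago2 instead of Dicer, had 4 and 5 counts in WT, 2 and 0 in Dgcr8_KO, and none in Drosha_KO, Dicer_KO or Ago12_KO, and was too rare to test. miR-1306, a hairpin in the Dgcr8 transcript, had 61 and 55 counts in WT, 0 and 3 in Dgcr8_KO, none in Drosha_KO or Dicer_KO, and 4 and 4 in Ago12_KO.

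Over all entries, 64 were higher and 205 lower in Dicer_KO by edgeR's quasi-likelihood test. The split was 84 to 106 with DESeq2 size factors, 6 to 429 unscaled and 99 to 80 with fragment-like entries out of the totals. Fibroblast or feeder markers had 2 of 11 higher and 5 lower, with miR-22-3p at -5.07 (edgeR adjusted p = 3.32e-07) and miR-10a-5p at 2.54 (edgeR adjusted p = 0.00110), and neural markers 4 of 7 lower, with miR-128-3p at -6.08 (edgeR adjusted p = 1.87e-05). Its only 2 counts were in Dicer_KO replicate 1, and without that library the fit gave -13.02, which no count supports. Both muscle markers tested were higher, with miR-499-5p at 4.84 (edgeR adjusted p = 1.67e-05). With counts left unscaled, 0 of them were called and their median turned to -1.30. Blood markers had 2 of 6 lower, and liver, gut and endoderm markers 2 of 3, while with fragment-like entries out of the totals 2 blood markers were higher and none lower.

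Dicer_KO against Drosha_KO sets the loss of the later cut beside the loss of the earlier one. miR-877-5p (log2 fold change -8.59, SE 0.57, edgeR adjusted p = 5.08e-07), miR-484 (-8.47, SE 0.46, edgeR adjusted p = 2.19e-07) and miR-1983 (-7.63, edgeR adjusted p = 2.12e-07) were lower in Dicer_KO, and miR-6240 (6.01, edgeR adjusted p = 2.12e-07) and miR-3963 (4.05, edgeR adjusted p = 5.58e-06) higher. miR-295-3p (-2.24, edgeR adjusted p = 2.68e-05) and miR-182-5p (-2.003, edgeR adjusted p = 4.82e-05) were lower, and both calls were lost with fragment-like entries out of the totals (0.292 and 0.517, with ranges of 5.82e-20 to 0.292 and 4.52e-15 to 0.517). miR-92a-3p, at 6320 ± 69.2 and 6674 ± 597 CPM, was not called (-0.08, edgeR adjusted p = 0.800), while DESeq2 size factors put it higher in Dicer_KO (1.19, edgeR adjusted p = 0.00393, range 3.99e-06 to 1). In all, 65 entries were higher and 146 lower. The split was 99 to 90 with DESeq2 size factors, 123 to 64 with fragment-like entries out of the totals, and 34 to 78 when only these groups were fitted. The median of all entries was -1.03, or -0.69 under TMM, 0 with DESeq2 size factors and -0.85 unscaled.

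The comparison of Ago12_KO with WT asks which miRNAs depend on Ago1 and Ago2. miR-92a-3p, at 154410 ± 26789 CPM, was not called (log2 fold change -0.01, SE 0.20, edgeR adjusted p = 0.965), though TMM put it lower (-0.66, edgeR adjusted p = 0.0304, range 1.24e-04 to 1). miR-182-5p was not called either (0.21, edgeR adjusted p = 0.457), and was at -0.44 under TMM and -0.09 without Ago12_KO replicate 2. miR-181a-2-3p (9.97, SE 0.64, edgeR adjusted p = 2.77e-06), miR-1247-3p (7.34, edgeR adjusted p = 1.02e-05), miR-181a-5p (6.36, edgeR adjusted p = 1.37e-05), miR-6539 (6.30, edgeR adjusted p = 1.99e-07), miR-205-3p (6.08, edgeR adjusted p = 2.64e-06), miR-146a-5p (6.02, edgeR adjusted p = 1.88e-05) and miR-21a-3p (5.40, edgeR adjusted p = 3.63e-06) rose. miR-181a-2-3p went to 449 CPM from 0.212 CPM in WT, below the floor of 3 counts. For miR-1247-3p the values were 417 CPM and 2.39 CPM, so the size of both rises is uncertain. miR-92a-1-5p, the partner strand of miR-92a-3p, rose by 5.02 (edgeR adjusted p = 1.62e-04) to 10.3% of the counts in replicate 1 and 2.58% in replicate 2.

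Among miRNAs that fell in Ago12_KO were miR-421-3p (-6.32, SE 0.54, edgeR adjusted p = 1.18e-05), miR-431-5p (-5.92, edgeR adjusted p = 0.00204), miR-301a-3p (-5.63, edgeR adjusted p = 2.77e-06), miR-702-3p (-5.56, edgeR adjusted p = 1.25e-04) and miR-1983 (-4.29, edgeR adjusted p = 7.11e-06), and miR-6944-3p, with no count, was at least 84.7-fold lower. miR-702-3p had 1 count in Ago12_KO, and without Ago12_KO replicate 2 the fit gave -8.83, which no count supports. miR-295-3p went to 37889 ± 5850 CPM (-1.42, SE 0.24, edgeR adjusted p = 4.76e-04). miR-484 (-1.16, edgeR adjusted p = 0.00894) and miR-877-5p (-1.10, edgeR adjusted p = 0.0230) fell, but without Ago12_KO replicate 1 (0.0776 and 0.186) or WT replicate 2 (0.0579 and 0.134) neither was called (miR-877-5p at -0.67 without Ago12_KO replicate 1), over ranges of 5.16e-06 to 0.0776 and 1.18e-05 to 0.186. miR-16-5p fell by 0.92 (edgeR adjusted p = 0.0104), lost without Ago12_KO replicate 2 (0.0780) or WT replicate 1 (0.0648), over a range of 3.81e-05 to 0.078. Of the miR-15/16 family 7 of 12 rose and 3 fell, which flips to 1 higher and 7 lower without scaling. Of the miR-17-92, miR-106a-363 and miR-106b-25 clusters 5 of 26 rose and 12 fell, and of the miR-290 to miR-295 cluster 1 of 14 rose and 5 fell, with no camera call for either.

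In the Dlk1-Dio3 cluster 39 of 63 members fell and 4 rose in Ago12_KO (40 and 4 adjusted over the list alone), with a median of -1.72 and a camera adjusted p = 0.00102, against adjusted p = 0.668 with an estimated correlation. miR-127-3p was at 30529 ± 218.8 CPM (-1.40, SE 1.38, edgeR adjusted p = 0.405), not called, and without Drosha_KO replicate 1 or Drosha_KO replicate 2 it was (edgeR adjusted p = 6.79e-05 and 2.30e-05, range 1.91e-06 to 0.562). The Sfmbt2 cluster, repeated hairpins in an intron of Sfmbt2, had 20 of 44 tested members higher and none lower, a direction that flips to 0 higher and 24 lower without scaling. miR-669a-3p rose by 1.88 (edgeR adjusted p = 0.00139). Camera gave adjusted p = 0.0139, against adjusted p = 0.668 with an estimated correlation, and miR-669a-5p, miR-669a-3p and miR-467a-5p of this cluster held only multiples of 12, 11 and 10. Blood markers had 4 of 6 higher and none lower, which flips to 2 and 3 without scaling, with a camera adjusted p = 0.0256, against adjusted p = 0.268 with an estimated correlation. miR-142a-3p rose by 4.21 (edgeR adjusted p = 1.18e-05) and miR-142a-5p by 3.58 (edgeR adjusted p = 1.47e-04). miR-192-5p (2.71, edgeR adjusted p = 2.44e-04) and miR-375-3p (3.05, edgeR adjusted p = 3.95e-04) of the liver, gut and endoderm list of 3 rose and the third fell, which flips to 0 higher and 1 lower without scaling. The neural list split evenly, with 3 of 7 higher and 3 lower. Among those that fell were miR-128-3p (-2.90, edgeR adjusted p = 1.39e-04) and miR-9-5p (-1.89, edgeR adjusted p = 0.00108).

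Over all entries, 28.7% of the 481 were higher and 25.8% lower in Ago12_KO by edgeR's quasi-likelihood test, against 109 and 179 under TMM and 16 and 336 unscaled. Both tested members of the miR-302 and miR-367 cluster rose, with miR-302a-5p at 3.95 (edgeR adjusted p = 2.09e-04), and 2 of 10 let-7/miR-98 members rose, but without scaling no miR-302 and miR-367 member was called and 8 let-7/miR-98 members were lower. Of 7 mirtrons 4 fell and none rose, and of bypassing hairpins 3 of 5 rose and 1 fell, against 0 and 2 unscaled. Of snoRNA-derived entries 3 of 5 rose and of tRNA or rRNA entries 2 of 4 rose and 1 fell, directions that also flip unscaled (0 and 2, and 0 and 1). Fibroblast or feeder markers had 4 of 11 higher and 2 lower, against 4 and 7 under TMM, and neural markers 3 of 7 higher and 3 lower.

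Ago12_KO against Dicer_KO separates cells that lack Argonaute proteins from cells that lack the duplex. miR-92a-1-5p (log2 fold change 7.88, SE 0.84, edgeR adjusted p = 2.50e-05), miR-92a-3p (4.61, SE 0.24, edgeR adjusted p = 3.66e-07), miR-192-5p (4.57, edgeR adjusted p = 2.25e-05), miR-295-3p (2.74, edgeR adjusted p = 8.46e-06) and miR-484 (2.57, edgeR adjusted p = 5.85e-04) were higher in Ago12_KO, the last not called with DESeq2 size factors (0.173, range 1.89e-06 to 0.364). miR-6240 (-5.08, edgeR adjusted p = 5.55e-07) and miR-3963 (-4.78, edgeR adjusted p = 2.50e-06) were lower. miR-182-5p was higher by 1.07 (edgeR adjusted p = 0.00338), but at -0.56 with DESeq2 size factors. In all, 185 entries were higher and 43 lower, against 70 and 76 with DESeq2 size factors, 352 and 6 unscaled and 60 and 83 with fragment-like entries out of the totals. Without Dicer_KO replicate 1 the counts were 116 and 28. The median of all entries was 2.38, or 2.01 under TMM, 0.77 with DESeq2 size factors and 4.21 unscaled. In Dgcr8_KO against Drosha_KO it was 0.13, or 0.44, 0 and 3.07.

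The balance of the 5p and 3p arms of a hairpin was compared with WT where both arms had a mean of 20 counts, a measure that library scaling does not move. In Ago12_KO the balance changed for 44 of 120 hairpins, 37 toward the arm that is minor in WT. The 5p arm of miR-21a made up 67.2% of its counts against 95.7% in WT, that of miR-290a 19.3% against 75.2%, that of miR-26b 68.7% against 97.2%, that of miR-27b 15.8% against 0.845% and that of miR-148a 21.6% against 3.87%. In Dicer_KO 51 of 108 changed, 45 toward the minor arm, with miR-295 at 57.2% 5p against 0.550%. In Drosha_KO 18 of 108 changed, 16 toward the minor arm, with miR-3068 at 75.4% 5p against 5.24%. In Dgcr8_KO 2 of 114 changed (11 at an unadjusted p under 0.05), miR-425, which had a single count there, and miR-291b. The hairpins named here were chosen after their values were seen. Several called hairpins in Drosha_KO and Dicer_KO had few or no mutant counts, so that the pseudocount set their value. Without any mutant count the arms come out equal, which fixes the direction toward the minor arm in advance. In Drosha_KO this held for miR-370, miR-425, miR-337, miR-540, miR-673, miR-676 and miR-15b. With at least 100 counts in each mutant library 2 of 18 changed in Drosha_KO (1 toward the minor arm and 1 toward the major arm) and 8 of 11 in Dicer_KO (5 and 3). With a pseudocount of 5, 32 changed in Dgcr8_KO, 74 in Drosha_KO, 83 in Dicer_KO and 88 in Ago12_KO, of which 28, 71, 78 and 76 moved toward the minor arm. A larger pseudocount draws the ratios of the shallower mutant libraries toward equal arms, so this direction is in part built in. With at least 100 counts in each mutant library 1 of 55 hairpins changed in Dgcr8_KO, toward the major arm. Without WT replicate 1 or WT replicate 2 the number of changed hairpins was 23 or 28 in Ago12_KO, 16 or 19 in Dicer_KO, 4 or 4 in Drosha_KO and 0 or 0 in Dgcr8_KO (4 and 6 at an unadjusted p under 0.05). It was 29 in Drosha_KO without Drosha_KO replicate 2, and in Dgcr8_KO 1 without Dgcr8_KO replicate 1 and 4 without Dicer_KO replicate 1 or Dicer_KO replicate 2.

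**Figure D5:**
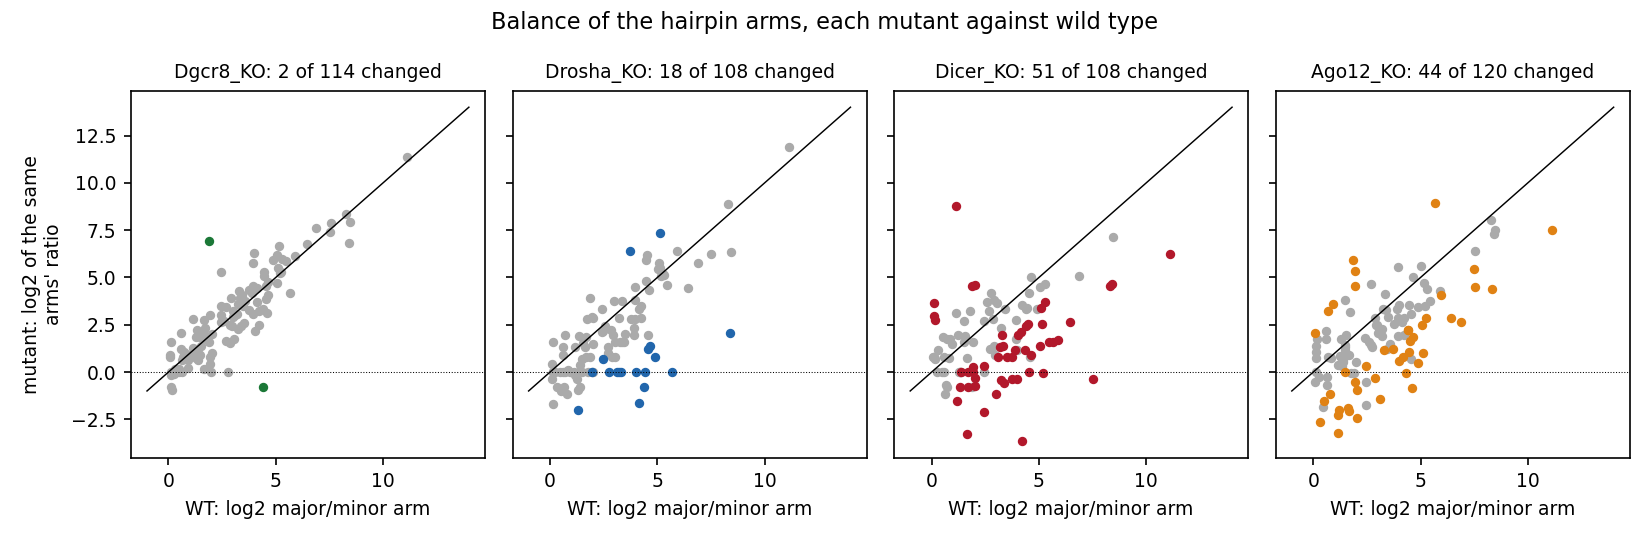
log2 ratio of the WT major to the WT minor arm in WT (horizontal) and of the same arms in each mutant (vertical), 1 point per hairpin, colored where limma's adjusted p is under 0.05, with the line of equal ratios. In Ago12_KO 37 of the 44 changed hairpins lie below the line.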

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

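Corrected repeat counts, fragment-like entries out of the totals, the minimum of 100 counts per mutant library and the Dlk1-Dio3 count were chosen after the results were seen. Over all alternatives, 325 of the recomputed counts stayed within 1.5 times their value and 64 did not. Of the values of named miRNAs 2727 kept their direction and their side of the threshold, 36 gained a call, 45 lost one and 48 reversed. Of the list tests 151 kept their side and 17 lost it, all 17 among the 56 tests with an estimated correlation. Every camera call printed in the results was among those lost, so none of them held with an estimated correlation. Of the list shares 280 stayed within 1 SD and 80 did not. The 180 shares that left out 1 library had to stay, since each of 2 values lies within 1 SD of their mean. With the tRNA or rRNA entries out of the denominator 18 of 90 moved, and without the most abundant entry 62 of 90 did. Low total counts limit Drosha_KO and Dicer_KO most, where 1 count is worth 22.1 to 26.7 CPM. The cause was not tested for any change below, except that no scaling leaves the difference in total counts in the fold changes.

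Without scaling, 51 miRNAs were higher and 329 lower in Dgcr8_KO, 5 and 399 in Drosha_KO, 6 and 429 in Dicer_KO, 16 and 336 in Ago12_KO, 348 and 5 in Dgcr8_KO against Drosha_KO, and 352 and 6 in Ago12_KO against Dicer_KO. Log2 fold changes reversed to -1.16 for miR-291a-5p, -1.47 for miR-127-3p and -1.94 for miR-182-5p in Dgcr8_KO. In Drosha_KO they reversed to -0.46 for miR-877-5p, -1.14 for miR-702-3p, -1.0036 for miR-484, -0.81 for miR-320-3p, -0.12 for miR-1839-5p, -0.49 for miR-1983, -4.04 for miR-291a-5p, -4.62 for miR-182-5p, -2.20 for let-7g-5p, -2.63 for miR-138-5p, -4.165 for miR-294-3p and -0.084 for miR-664-5p. In Dicer_KO they reversed to -0.85 for miR-499-5p, -5.57 for miR-15b-5p, -3.15 for miR-10a-5p, -0.63 for miR-5099 and -1.97 for miR-295-5p, and in Ago12_KO to -0.27 for miR-192-5p, -1.08 for miR-669a-3p and -2.74 for miR-182-5p. In Dgcr8_KO against Drosha_KO miR-877-5p reversed to 2.14 and miR-484 to 2.19. Calls lost without scaling in edgeR with their direction kept were miR-142a-5p in Dgcr8_KO (0.55, adjusted p = 0.381, range 2.37e-14 to 0.381), miR-5126 in Dicer_KO (1.70, adjusted p = 0.121, range 7.22e-83 to 0.121), and in Ago12_KO miR-142a-5p (0.65, adjusted p = 0.329, range 1.15e-16 to 0.329), miR-302a-5p (1.14, adjusted p = 0.115, range 2.71e-10 to 0.115) and miR-375-3p (0.19, adjusted p = 0.775, range 4.35e-11 to 0.775).

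TMM reversed miR-15b-5p in Dicer_KO to -0.15, miR-182-5p in Ago12_KO to -0.44 and miR-92a-3p in Dicer_KO against Drosha_KO to 0.27. DESeq2 size factors, in edgeR or DESeq2, reversed miR-320-3p to 0.48 and 0.49 and miR-182-5p to 0.52 and 0.52 in Dicer_KO, miR-182-5p to -0.042 and -0.042 in Ago12_KO, miR-92a-3p to 1.19 and 1.19 in Dicer_KO against Drosha_KO, and miR-182-5p to -0.56 and -0.56 in Ago12_KO against Dicer_KO. In edgeR they left 106 lower in Dicer_KO, 99 higher and 90 lower in Dicer_KO against Drosha_KO, and 70 higher and 76 lower in Ago12_KO against Dicer_KO. DESeq2 with its own size factors gave 103 higher and 102 lower in Dicer_KO, 75 lower in Dgcr8_KO against Drosha_KO, 120 higher and 93 lower in Dicer_KO against Drosha_KO, and 70 higher and 87 lower in Ago12_KO against Dicer_KO, and with column totals 63 lower in Dgcr8_KO against Drosha_KO. With fragment-like entries out of the totals, 99 were higher and 80 lower in Dicer_KO, 123 and 64 in Dicer_KO against Drosha_KO, and 60 and 83 in Ago12_KO against Dicer_KO, and reversed values were 1.07 for miR-320-3p and 1.11 for miR-182-5p in Dicer_KO, 0.11 for miR-92a-3p in Ago12_KO, 1.735 for miR-92a-3p in Dicer_KO against Drosha_KO and -0.77 for miR-182-5p in Ago12_KO against Dicer_KO. The entries left out were chosen for their high Dicer_KO values, so the upward move of all others in Dicer_KO was set by that choice. Corrected repeat counts put miR-92a-3p in Ago12_KO at 0.0036.

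No filter gave 259 higher in Dgcr8_KO, and fitting only the groups compared gave 34 higher and 78 lower in Dicer_KO against Drosha_KO. The replicate block changed no call of a named miRNA or list, as with miR-182-5p in Dicer_KO (-0.86), and differences between replicates 1 and 2 correlated across groups at -0.0648 to 0.136 over miRNAs, which are not independent replicates. Hairpins with a changed arm balance in Dgcr8_KO, Drosha_KO, Dicer_KO and Ago12_KO numbered 1, 7, 22 and 28 with a mean of at least 100 per arm, 32, 74, 83 and 88 with a pseudocount of 5, and 1, 2, 8 and 32 with at least 100 counts in each mutant library.

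Leaving out 1 library, the counts higher and lower ranged from 139 to 186 and 147 to 218 in Dgcr8_KO, 118 to 143 and 112 to 158 in Drosha_KO, 49 to 71 higher in Dicer_KO (where the count lower stayed within 1.5 times its value), 115 to 163 and 86 to 146 in Ago12_KO, 11 to 50 and 18 to 48 in Dgcr8_KO against Drosha_KO, 47 to 64 and 100 to 141 in Dicer_KO against Drosha_KO, and 116 to 195 and 28 to 50 in Ago12_KO against Dicer_KO. Dlk1-Dio3 members lower in Drosha_KO ranged from 32 (without Drosha_KO replicate 1) to 52 (without Drosha_KO replicate 2), and changed hairpins from 0 to 4 in Dgcr8_KO, where 0 calls by limma stood beside 4 and 6 at an unadjusted p under 0.05, from 4 to 29 in Drosha_KO, 16 to 54 in Dicer_KO and 23 to 54 in Ago12_KO. miR-92a-3p ranged from -0.20 to 0.15 in Ago12_KO and from -0.17 to 0.016 in Dicer_KO against Drosha_KO, and miR-182-5p from -0.092 to 0.46 in Ago12_KO. The libraries without which a call was lost are named with their values in the results.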

Other observations

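Of the tests below, only the choice of the minor arm by 1 WT library was set before its result was seen. Set against the reads of mirtrons and Drosha-bypassing hairpins, the miR-290 to miR-295 cluster had 99.4 ± 6.68 reads per such read in WT, 5.01 ± 0.117 in Dgcr8_KO and 3.83 ± 0.810 in Drosha_KO (SD, n = 2), 19.8-fold and 26.0-fold below WT. The miR-17-92, miR-106a-363 and miR-106b-25 clusters had 97.9 ± 6.75, 0.651 ± 0.0107 and 0.253 ± 0.0789, 150-fold and 387-fold below WT. These ratios need no library scaling, but a change in the reference reads would move them too.

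In Dicer_KO, miR-295-5p was about as abundant as miR-295-3p, at 7346 ± 1558 and 5671 ± 1452 CPM (SD, n = 2), and ahead of it in 1 of the 2 libraries. In WT miR-295-5p was at 558 ± 16.7 CPM (log2 fold change 3.72, edgeR adjusted p = 6.77e-06), while without scaling it was at -1.97. Among the other members, the 5p arm made up 51.4% of miR-294 counts against 2.66% in WT, and 9.005% of miR-290a counts against 75.2%, while miR-293 (92.8% against 51.5%) and miR-291b (97.6% against 78.6%, with 41 counts in Dicer_KO) changed toward the arm that is major in WT.

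Reads of canonical miRNAs remained in Dgcr8_KO and Drosha_KO. Carryover of WT reads or cells would leave each abundant canonical miRNA at about 1 ratio to WT, but over 81 canonical miRNAs with at least 1000 CPM in WT the SD of the log2 ratio was 2.44 in Dgcr8_KO, against 0.275 from the spread between replicates. miR-181d-5p was at 0.0245% and miR-291a-5p at 44.4% of its WT counts. In Drosha_KO the SD was 2.41 against 0.347 over the 65 outside the Dlk1-Dio3 cluster, which was left out after its values were seen, and 2.82 against 1.26 over all 81, which leaves the cluster undecided. Carryover of a smaller share, and processing that does not need either subunit, stay open, and no biological explanation was tested.

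Dlk1-Dio3 reads were nearly missing from Drosha_KO replicate 1. Sampling at low depth was argued against, since the upper 95% Clopper-Pearson limit of 0.0331% lies below the lower limit of 10.6% in replicate 2. A library of another profiled group was argued against too, because outside the cluster replicate 1 correlated at 0.958 with Drosha_KO replicate 2 and at 0.901 with the next best, Dgcr8_KO replicate 1, over 437 entries, which are not independent replicates. A difference between clones or cultures at this imprinted cluster may explain the gap, but the labels name none for Drosha_KO and it was not tested.

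In Ago12_KO, 37 of 44 hairpins with a changed arm balance (84.1%) moved toward the arm that is minor in WT. With the minor arm set by WT replicate 1, it was higher in WT replicate 2 for 60% of 120 hairpins (95% interval 50.7 to 68.8) and in Ago12_KO for 80.0%, and with the replicates exchanged for 42.5% and 76.7%, which argues against the choice of arm as the whole cause. Entries that hold only multiples of a number, as if counted at several hairpins, were in 1 of the 37 (2.70%, 0.0684 to 14.2). They were in only 7 of all 120 hairpins (5.83%, 2.38 to 11.65), so they could not have been in most of the 37. They therefore cannot be the whole cause, but the 2.70% was no test of them. Of all 120 hairpins, called or not, the minor arm's share lay above both WT shares by its 95% limit in both Ago12_KO libraries for 57 (47.5%, 38.3 to 56.8) and below both for 12 (10%, 5.27 to 16.8), which argues against few reads as the whole cause. With at least 100 counts in each mutant library 25 of 32 changed hairpins moved toward the minor arm in Ago12_KO (78.1%, 60.03 to 90.7), against 5 of 8 in Dicer_KO and 1 of 2 in Drosha_KO, where 45 of 51 and 16 of 18 did without that minimum. The latter numbers include hairpins without any mutant count, whose direction was fixed by the pseudocount. Reads shared between similar hairpins without such multiples stay open, and so does a loss of the strand choice that Argonaute proteins make, which may account for some of the shift but was not tested.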
